A study of Mus musculus with 2 samples.

How the data were processed

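Plasmid conditions were compared in mouse retina by droplet single-cell RNA sequencing. Plasmid was injected under the retina on postnatal day 0 (0.5 µL at 5 µg/µL) and driven into cells by electric pulses, and retinas were collected at postnatal day 10. One condition carried Pou4f2 with GFP and the other GFP alone. Retinas were dissociated with papain, several retinas were pooled with a target of 30000 cells, and live GFP-positive cells were sorted before library preparation. Each condition gave 1 library, with the pool of retinas as the only sample, so no comparison across samples could be tested and no p-value is given.

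The deposited matrices hold counts: the authors' Cell Ranger 7.0.1 output against mm10 lists UMIs per gene and barcode, unnormalised, over 32289 features of which 4 are added sequences. Cell Ranger and Seurat 4.3.0.1 and 5.1.0 are the tools named in the submitters' processing notes. The deposited cell table gives, for each retained barcode, 2 columns of class labels made by the authors, and a further 29866 cells of another study in that table were not used. How those labels were made is not given in the sources used here. The cells kept here are those of the table. They are the barcodes with more than 1200 genes, fewer than 25000 UMIs and less than 4% mitochondrial UMIs, apart from 1 barcode of the Pou4f2 library and 3 of the GFP library that met these limits and were left out. Kept cells numbered 9187 of 12124 barcodes (75.8%) in the Pou4f2 library and 7722 of 13009 (59.4%) in the GFP library. The second label column was used, which holds the class called rgc-like. In the first column the same cells carry other labels, mostly classes 1, 2, 3 and 4.

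Counts were summed over the cells of a library or of a class and expressed as UMIs per 1000000 (CPM) of that sum. Sums have exact Poisson 95% intervals, ratios of 2 sums have exact conditional binomial 95% intervals, and shares of cells have exact Clopper-Pearson 95% intervals. These cover counting error only, and not the variation between retinas or pools. For sums and ratios they also leave out the variation between cells. A gene with 0 UMIs in one arm was given a floor of 3 counts in that arm. For most shares of cells with a UMI, each cell was thinned at random to 2000 UMIs, and 123 cells of the Pou4f2 library and 159 of the GFP library with fewer UMIs were left out of those shares. Shares of cells with Sncg, Stmn2, Grp, Sst or Rgs5 are unthinned, as are those with Pou4f2 in class 3 and in barcodes outside the cell table.

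Comparisons were the whole libraries, each class with at least 100 cells in both libraries, each class found mainly in one library (at least 80% of its share) against Rods of the same library and against the whole GFP library, cells with against cells without a Pou4f2 UMI within the Pou4f2 library, and the joint presence of retinal ganglion cell (RGC) and rod genes in single cells. Genes were named by size: the 12 highest and 12 lowest ratios among genes with at least 200 UMIs over both arms, at least 20 CPM in the higher arm and an interval that excludes 1, and the 5 highest and 5 lowest within each of the 4 largest classes. Pou4f2, mitochondrial, ribosomal protein, haemoglobin and sex-linked genes and predicted genes with number names were left out of the ranking. Members of lists were named as up to 4 with the most UMIs and up to 2 with the largest log2 ratio. A few genes that these rules name are not reported here. These choices and 23 gene lists were fixed before the data were examined. For a list, members with at least 50 UMIs were measured, and the text gives the median log2 ratio, how many members were higher or lower by at least 1.5-fold with an interval that excludes 1, and the percentile of the median among 10000 random lists of the same size matched on expression in 20 bins. This percentile describes these libraries and is not a p-value.

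The lists covered RGC general, RGC transcription factor, RGC subtype, axon growth and guidance, neurofilament and cytoskeleton, projection neuron excitability, rod, photoreceptor fate, cone, bipolar, Müller glia, amacrine, horizontal, proliferating progenitor, neurogenic, microglia, endothelial, pericyte, retinal pigment epithelium, astrocyte, red blood cell, immediate early and dissociation, and stress and apoptosis genes. The lists share some genes, for example Isl1 and Ebf1. Alternatives were median-of-ratios scaling, scaling without the 20 most abundant genes, thinning to 1000 UMIs, other count minimums, all barcodes, cells without doublets marked by Scrublet in each library, a mean in place of the median, at least 2 UMIs or genes for detection, and an own Leiden clustering of both libraries without Pou4f2, GFP and sex-linked genes. Scrublet marked 2.75% of the Pou4f2 library and 0.712% of the GFP library; marked cells were kept in the main results. 3 further alternatives were added after the data had been seen. Coordinates are from GENCODE M21 on GRCm38.

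The intervals were checked on simulated Poisson counts with known changes. This is the model the intervals assume, so coverage near 95% was set in advance and checks the calculation only. Real UMIs clump in cells. In Rods of the Pou4f2 library the variance over mean ran from 1.22 (Glul) to 4.33 (Pcp2) for marker genes of other classes. For GFP in Rods of the GFP library it was 19.3, so real intervals can be too narrow. They covered the true value for 95.4% of unchanged genes in the whole comparison, 95.2% within Rods and 95.7% within Müller glia. Genes changed 2-fold were separated from no difference in 100% of cases in each of these. A simulated list of unchanged genes fell at percentile 0.11 within Rods with a median log2 ratio of -0.06, so an extreme percentile with a median near 0 shows little. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9.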

Results

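The data are UMI counts of single sorted retinal cells from mice that received either a Pou4f2 and GFP plasmid or a GFP plasmid as newborns, collected at postnatal day 10. There was 1 library per group. The Pou4f2 library held 9187 kept cells and 74312586 UMIs, with a median of 5951 UMIs and 2850 genes per cell, and the GFP library held 7722 kept cells and 51568701 UMIs, with a median of 4554.5 UMIs and 2285.5 genes. Pou4f2 encodes a transcription factor of retinal ganglion cells (RGCs), the projection neurons of the retina. The labels pose the question of whether late progenitors given Pou4f2 form RGC-like neurons. The authors' classes were Rods, Bipolar, MG (Müller glia), Amacrine, Cones, rgc-like and the numbered classes 1 to 4.

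Pou4f2 transcript was abundant in the Pou4f2 library and was not detected in the GFP library. The gene (ENSMUSG00000031688, chromosome 8, 78433010 to 78436645, minus strand) had 11545 UMIs, or 155 CPM [153–158], in the Pou4f2 library. In the GFP library it had 0 UMIs, with an upper limit of 0.0715 CPM. In thinned cells 14.2% [13.4–14.9] of the Pou4f2 library had a Pou4f2 UMI, and 30.2% did unthinned. With at least 2 UMIs required the thinned share was 3.82%, and with cells thinned to 1000 UMIs it was 8.26%. None of 7563 thinned cells of the GFP library did. UMIs of the plasmid and of the endogenous gene could not be told apart.

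Pou4f2 was spread unevenly over the classes of the Pou4f2 library. Rgc-like cells were at 674 CPM, class 2 at 278 CPM, class 1 at 144 CPM, class 4 at 104 CPM and Müller glia at 65.9 CPM. Class 3, of 23 cells, was at 1259 CPM, with UMIs in 13.0% of its cells. Levels were 26.2 CPM in Bipolar, 25.3 CPM in Cones, 15.9 CPM in Rods and 12.9 CPM in Amacrine cells. Among thinned cells, 50.6% [47.5–53.7] of rgc-like cells had a Pou4f2 UMI, against 3.14% [2.54–3.82] of Rods, at median depths of 9176 and 3708 UMIs, and unthinned these shares were 87.6% and 5.60%. GFP, the electroporation marker, was at 3285 CPM in rgc-like cells, 1708 CPM in class 2 and 802 CPM in class 1. It was at 86.7 CPM in Rods of the Pou4f2 library and 366 CPM in Rods of the GFP library. Pou4f2 UMIs per GFP UMI were 0.193 over the library, and ranged from 0.145 in Amacrine cells to 0.209 in Bipolar cells.

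**Figure D1:**
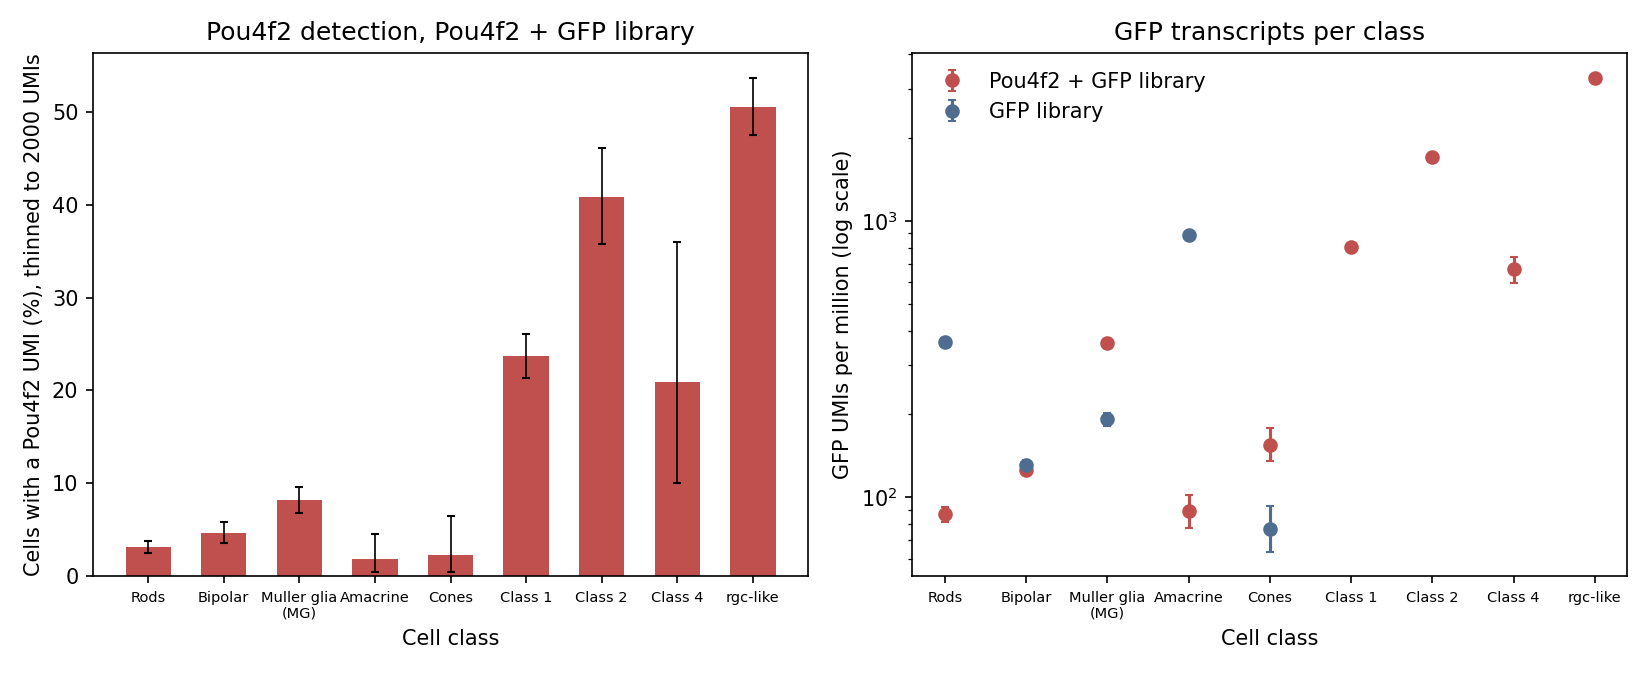
Left, share of cells thinned to 2000 UMIs with a Pou4f2 UMI in each class of the Pou4f2 library, with exact binomial 95% intervals. Right, GFP level in CPM on a log scale by class and library, with exact Poisson 95% intervals; the Pou4f2 share was 50.6% in rgc-like cells and 3.14% in Rods, and GFP was at 3285 and 86.7 CPM there.

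The makeup of the sorted cells differed between libraries. Rods were 34.2% [33.2–35.2] of the Pou4f2 library and 67.2% [66.2–68.3] of the GFP library. The rgc-like class was 11.3% [10.67–11.97] of the Pou4f2 library (1039 cells) and 0.0389% of the GFP library (3 cells). Class 1 was 14.2% against 0.0777%, and classes 2 and 4 were 3.99% and 0.468% of the Pou4f2 library and 0 of 7722 cells in the GFP library [0–0.0478]. Together these 4 classes were 29.9% of the Pou4f2 library and 0.117% of the GFP library.

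Müller glia, the radial glia of the retina, were 16.6% [15.8–17.3] of the Pou4f2 library and 6.58% [6.04–7.15] of the GFP library. Bipolar cells were 15.2% against 19.4%, Amacrine cells 2.41% against 4.35%, Cones 1.44% against 1.74%, and class 3 0.250% against 0.583%. Among cells outside classes 1, 2, 4 and rgc-like, Rods were 48.8% against 67.3%, Müller glia 23.6% against 6.59% and Bipolar cells 21.7% against 19.4%. There were 1.09 Müller cells per Bipolar cell in the Pou4f2 library and 0.339 in the GFP library. The GFP gate and the number of retinas pooled can set such shares. An own clustering without Pou4f2 and GFP put 53.7% of the Pou4f2 library in rod clusters. Of the rgc-like cells, 43.5% lay in a cluster with 18 rod markers but no rod gene among its leading genes (568 cells, none of the GFP library), 31.1% in a cluster with RGC general markers (362 cells, none of the GFP library) and 16.4% in a cluster with 16 Müller markers and 14 of another list, which had Calb2 and Sncg but no Müller glia gene among its leading genes.

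**Figure D2:**
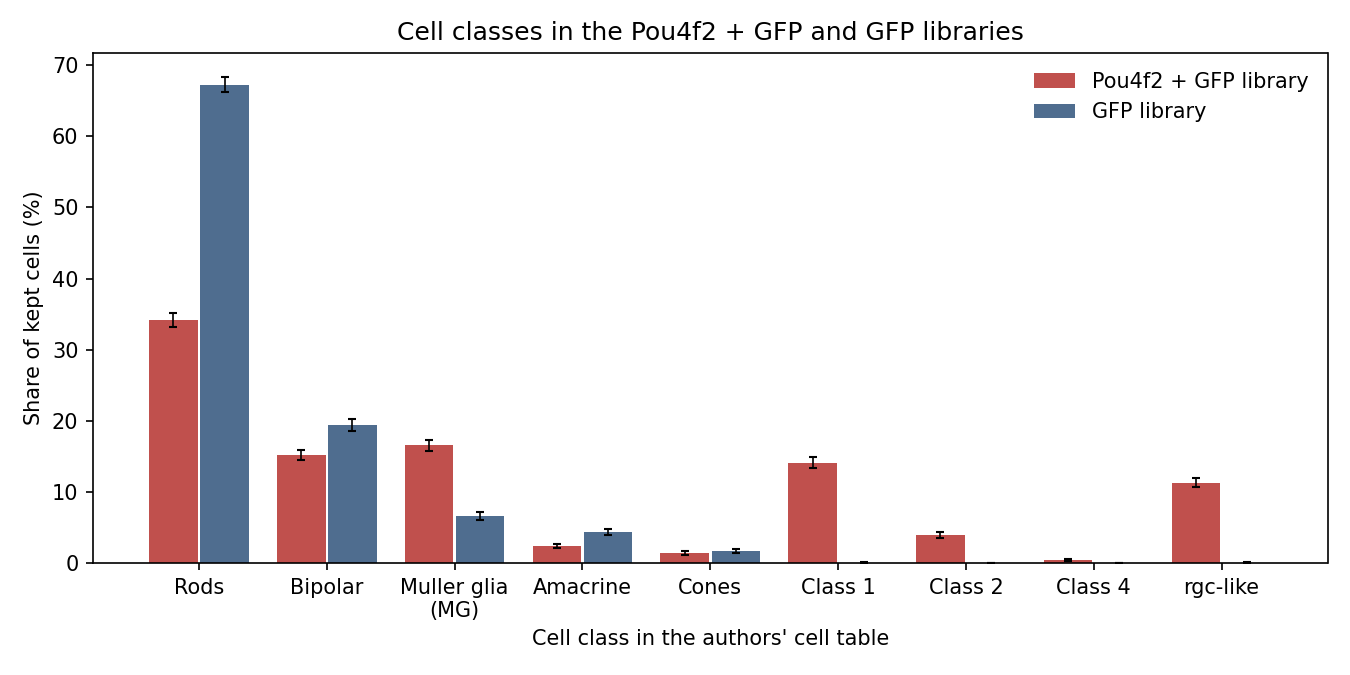
Share of kept cells in each class, in percent, by library, with exact binomial 95% intervals. Rods were 34.2% of the Pou4f2 library and 67.2% of the GFP library, and rgc-like cells were 11.3% and 0.0389%.

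Over whole libraries, RGC genes were higher in the Pou4f2 library and rod and bipolar genes were lower. Sncg, which encodes gamma-synuclein (chromosome 14, 34370274 to 34374789), was at 219 against 0.252 CPM, a ratio of 868 [507–1630]. Calb2, which encodes the calcium-binding protein calretinin (chromosome 8, 110137502 to 110168210), was at 551 against 22.6 CPM, a ratio of 24.4 [23.0–25.9]. The other genes with the highest ratios were Mme (142), Shisal2b (88.6), Slc17a8 (54.7), Islr2 (54.0), Evc2 (37.3), Grin2a (33.4), Hs3st2 (29.9), Car3 (29.6), Pcolce2 (27.9) and Mctp1 (26.1). The lowest was Prss56, a serine protease gene (chromosome 1, 87183313 to 87188405), at 30.4 against 173 CPM, a ratio of 0.176 [0.168–0.185]. Next came Rgs5 (0.227), Adamts19 (0.297), Lamp5 (0.311), Dync1i1 (0.332), Asic2 (0.350), Bc1 (0.374), Nkain2 (0.409), Pdzph1 (0.412), Gnat1 (0.416), Sebox (0.424) and Guca1b (0.424). Gnat1 and Guca1b encode rod phototransduction proteins.

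Of 20 RGC general genes measured, 17 were higher and 1 was lower, with a median log2 ratio of 2.40 (percentile 100). Gap43, a growth cone protein gene, was at 185 against 32.8 CPM, Nrn1 at 12.3 against 0.136 CPM and Ebf1 at 217 against 63.7 CPM, while Isl1, which bipolar cells also express, was at 328 against 550 CPM. RGC transcription factors had a median of 0.65 (12 higher and 1 lower of 22), RGC subtype genes 0.32 (8 and 3 of 24), axon growth genes 0.46 (10 and 1 of 29), neurofilament and cytoskeleton genes 0.53 (8 and 0 of 17) and projection neuron excitability genes 0.08 (4 and 2 of 20). Of 24 rod genes 0 were higher and 15 lower, with a median of -0.65 (percentile 0), and Sag was at 2305 against 3627 CPM. Of 20 bipolar genes 0 were higher and 12 lower, with a median of -0.72, and Pcp2 was at 524 against 1072 CPM. Photoreceptor fate genes had a median of -0.48 (0 and 3 of 11) and cone genes -0.42 (0 and 1 of 13). Müller glia genes had a median of 0.99 (17 and 0 of 20), with Rlbp1 at 813 against 298 CPM, and the share of Müller glia differed in the same direction. Amacrine genes had a median of -0.33 (3 and 6 of 15), horizontal cell genes 0.47 (5 and 1 of 11), proliferating progenitor genes 1.31 (12 and 0 of 15) and neurogenic genes -0.44 (3 and 5 of 15). Of the progenitor list, Hes5 was at 171 against 69.0 CPM and Top2a at 3.90 against 0.659 CPM. Class shares differed between the libraries, and whole-library medians do not separate them from levels within a class.

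**Figure D3:**
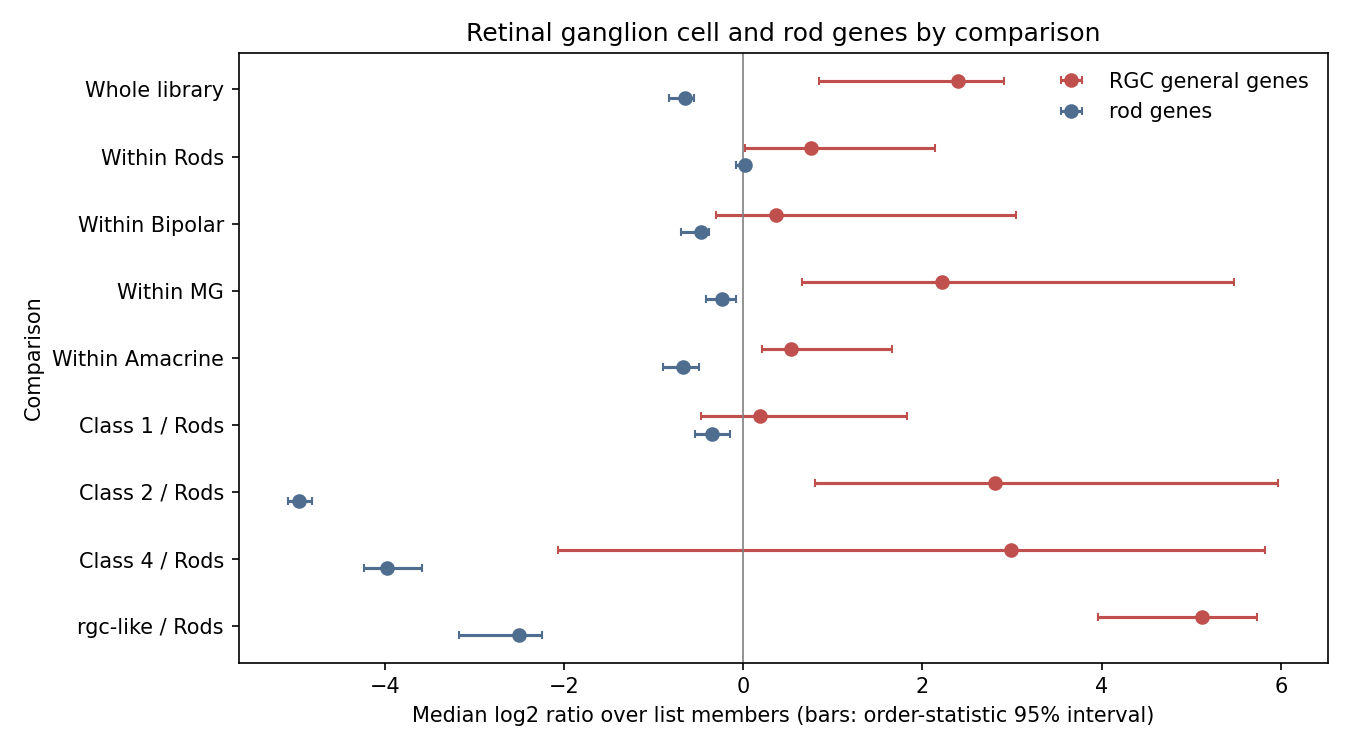
Median log2 ratio of the RGC general genes and of the rod genes in each comparison (Pou4f2 library over GFP library, or a class over Rods), with order-statistic 95% intervals of the median. Over whole libraries RGC general genes stood at 2.40 and rod genes at -0.65, and in rgc-like cells over Rods at 5.12 and -2.50.

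Within Rods the rod program was at a like level in both libraries. Of 24 rod genes 0 were higher and 0 lower, with a median of 0.02. The comparison covers only cells that carry the Rods label. GFP was at 86.7 against 366 CPM in them, and 14.3% of thinned Rods of the Pou4f2 library had a GFP UMI. In class 1 of that library GFP was at 802 CPM. The like level thus says little of rod-type cells that took up the plasmid. RGC general genes had a median of 0.76 (7 higher and 2 lower of 13), from low levels: Sncg was at 8.96 against 0.328 CPM and Stmn2 at 12.4 against 2.67 CPM. The highest ratios were Calb2 at 24.6 against 2.67 CPM (9.21 [6.92–12.4]), Scg2 (8.22), Ccdc175 (5.09), Rlbp1 (2.28) and Fosb (2.26), and the lowest were Nkain2 (0.209), GFP (0.237), Asic2 (0.337), Bc1 (0.382) and Eno1b (0.416). Müller glia genes, which rods should lack, had a median of 0.50 (8 and 0 of 18) in the same cells. RGC transcription factors had a median of 0.11, axon growth genes 0.10 (-0.025 with members of at least 200 UMIs), bipolar genes -0.20 and proliferating progenitor genes 0.31.

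Counts of a few neuronal genes were higher in Bipolar cells of the Pou4f2 library, and bipolar genes were at nearly the same level. Free RNA was not subtracted, and Cones also had Sncg at 17.1 CPM against 0 UMIs and Stmn2 at 12.7 against 1.41 CPM. In thinned Cones both log2 ratios turned to -0.56, from a few UMIs against the floor of 3. In Bipolar cells Sncg was at 21.9 against 0.0546 CPM (1 UMI in the GFP library), a ratio of 402 [71.7–15921]. Stmn2, which encodes a microtubule regulator of growing axons, was at 55.2 against 3.38 CPM. Nell1 (26.0), Epha6 (16.8) and Cntnap4 (12.5) followed, and the lowest were Prss56 (0.0134), Pmch (0.0469), Eno1b (0.408), Hopx (0.411) and Bc1 (0.444). RGC general genes had a median of 0.37 (6 and 0 of 14), RGC transcription factors 0.21 (3 and 0 of 15), axon growth genes 0.28 (7 and 0 of 29), bipolar genes -0.07 (1 and 1 of 20), rod genes -0.47 (0 and 8 of 24), Müller glia genes 0.31 (6 and 1 of 19), amacrine genes -0.20 (1 and 3 of 10) and proliferating progenitor genes 0.42 (3 and 0 of 10). The amacrine median turned to 0.42 with cells thinned and to 0.45 with members of at least 200 UMIs.

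Müller glia of the Pou4f2 library had higher levels of RGC general genes and of Calb2 than Müller glia of the GFP library, at close to equal levels of most Müller genes. Calb2 was at 427 against 1.37 CPM, a ratio of 312 [165–684]. Sncg was at 111 against 0.152 CPM (1 UMI), a ratio of 733 [131–28965], Hs3st2 at 116 against 0.456 CPM (3 UMIs), a ratio of 255 [87.1–1237], and Dok5 at 45.8 against 0.456 CPM (3 UMIs), a ratio of 100 [34.3–488]. Mme, which encodes a membrane peptidase, was at 49.4 CPM against 0 UMIs, at least 108-fold higher. The lowest were Prss56 at 112 against 1194 CPM (0.0939 [0.0895–0.0984]), Adamts19 (0.127), Pcp2 (0.223), Slc26a7 (0.233) and Nkain2 (0.275). RGC general genes had a median of 2.22 (9 and 0 of 12) and Müller glia genes -0.12 (0 and 1 of 20), with Glul at 2766 against 2469 CPM. RGC transcription factors had a median of 0.24 (7 and 0 of 16), with Ebf1 at 196 against 4.41 CPM, and axon growth genes -0.07 (4 and 3 of 25). Rod genes had a median of -0.24 (1 and 3 of 24), bipolar genes -0.37 (1 and 4 of 13), proliferating progenitor genes 0.65 (8 and 1 of 15) and neurogenic genes -0.13 (0 and 3 of 12). With cells thinned the bipolar median turned to 0.068 and the neurogenic one to 0.0089. Free RNA was not subtracted, so values of rod and bipolar genes, Pcp2 among them, are not read as expression by Müller glia.

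Different own clusters held most Müller glia of the 2 libraries. A cluster led by cells of the Pou4f2 library held 855 (56.2%) of its Müller glia, and 1 cell of the GFP library. The cluster shared by both libraries held 560 (36.8%) of the Pou4f2 library's and 472 (92.9%) of the GFP library's. In the first cluster Calb2 was at 674 CPM and Prss56 at 2.42 CPM, and in shared-cluster cells of the Pou4f2 library at 11.1 and 279 CPM. Within the shared cluster RGC general genes had a median of 0.89 (5 and 0 of 8), from low levels. Sncg was at 4.63 against 0.155 CPM and Calb2 at 11.1 against 1.24 CPM there. In the Pou4f2 library both were below their CPM in Rods. Median depths of these Müller glia and of Rods were 13845 and 3708 UMIs, so this order need not hold in UMIs per cell. Free RNA was not subtracted. The medians of Müller glia, proliferating progenitor and neurogenic genes turned to 0.038, -0.016 and 0.045 in the shared cluster. The clusters were made from expression, so cells that share one are alike by construction. Medians near 0 within it, and differences between clusters, can follow from that.

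Amacrine cells of the Pou4f2 library had more Npy, the neuropeptide Y gene, at 368 against 24.6 CPM (14.9 [11.97–18.81]). Nefm, a neurofilament gene (6.91), Crybb3 (4.76) and Etl4 (4.73) were also among the highest. The mix of own clusters in this class differed: the cluster with Npy among its leading genes held 37.1% against 30.1% of Amacrine cells, and 3 others held 43.9% against 29.5%, 10.9% against 22.0% and 8.14% against 18.2%. In the Pou4f2 library 38 cells of first label Amacrine were in the rgc-like class. GFP was lower at 89.0 against 890 CPM (0.100), as were Vip (0.232), Rprm (0.250), Il1rapl2 (0.290) and Gnat1 (0.302). RGC general genes had a median of 0.54 (6 and 1 of 12), amacrine genes 0.30 (6 and 1 of 15), rod genes -0.67 (0 and 13 of 24), bipolar genes -0.64 (1 and 5 of 12) and Müller glia genes 0.46 (6 and 2 of 13). Free RNA was not subtracted. A rod UMI was in 87.3% against 95.2% of thinned Amacrine cells, and Rods were 34.2% against 67.2% of the libraries. Values of rod, bipolar and Müller genes, Gnat1 among them, are thus not read as expression by Amacrine cells. In Cones 3 RGC general genes were measured, with a median of 0.09.

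The rgc-like class carried many RGC and axon genes at high levels and rod genes at low levels relative to Rods of the same library. Sncg was at 765 CPM, Stmn2 at 1037, Ebf1 at 704, Tubb3 at 578, Uchl1 at 506, Gap43 at 484 and Sox11 at 351 CPM. Gnat1, a rod phototransduction gene, was at 53.8 against 730 CPM, a ratio of 0.0736 [0.0674–0.0802]. Slc17a6, the vesicular glutamate transporter gene of RGCs, was at 9.17 CPM, Thy1 at 22.8, Rbpms at 27.7 and Pou4f1 at 4.44 CPM. Sncg was found in 55.2% and Stmn2 in 54.0% of rgc-like cells. Class 2 had higher levels of Sncg (1167 CPM), Rbpms (130) and Pou4f1 (18.5). It had lower levels of Stmn2 (16.3), Gap43 (295), Thy1 (8.49) and Slc17a6 (0 UMIs). Uchl1, Slc17a6, Thy1, Rbpms and Pou4f1 were chosen after their values were seen, as was the comparison with class 2. How the rgc-like label was made is not given in the sources used here, so the levels of RGC genes in this class cannot be taken as independent of it.

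By the ratio over Rods the highest in rgc-like cells were Islr2 at 127 against 0.484 CPM (263 [120–717]), Grp, the gastrin-releasing peptide gene (185), Brinp3 (129) and Sst, the somatostatin gene, at 31.0 CPM against 0 UMIs, at least 128-fold higher. Grp was found in 2.31% and Sst in 0.385% of the 1039 rgc-like cells. Nrg3os (299 [82.5–2480], 2 UMIs in Rods) and Hcrtr2 (294 [52.3–11662], 1 UMI), with Mecom, Resp18, Cnr1, Lhx1os, Olig3 and St8sia6, each with 3 or fewer UMIs in Rods, completed the 12 highest. Among the lowest were Guca1b (0.0472), AI847159 (0.0525), Gucy2f (0.0620), Lrp4 (0.0629), Aipl1 (0.0657), Ppara (0.0660), Synpo2 (0.0672), Wdr63 (0.0684), Susd3 (0.0730), Gnat1 (0.0736) and Pdzph1 (0.0765). RGC general genes had a median of 5.12 (19 and 1 of 20, percentile 100), RGC transcription factors 4.45 (19 and 0 of 19), RGC subtype genes 2.51 (14 and 3 of 18), axon growth genes 3.51 (21 and 4 of 29), neurofilament genes 4.33 (14 and 2 of 17), excitability genes 3.90 (15 and 2 of 20), bipolar genes 1.59 (13 and 1 of 17), Müller glia genes 0.83 (13 and 2 of 18), proliferating progenitor genes 1.57 (4 and 1 of 7) and neurogenic genes 1.15 (6 and 3 of 12). Rod genes had a median of -2.50 (0 and 24 of 24). With the own RGC general cluster found in the Pou4f2 library, which held 31.1% of rgc-like cells, in place of the class and own rod clusters in place of Rods, the rod median was -4.75, and those of Müller glia, proliferating progenitor and neurogenic genes turned to -0.39, -0.95 and -0.61. Against the whole GFP library, RGC general genes had a median of 3.50 (18 and 2 of 20), rod genes -1.33 (0 and 22 of 24) and Sncg a ratio of 3033.

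In classes 1, 2 and 4 the rod medians were lower and the RGC general medians higher than in Rods. Class 1 kept high rod levels: rod genes had a median of -0.35 over Rods (0 and 5 of 24) RGC general genes 0.19 (3 and 0 of 11), RGC transcription factors 0.25 (5 and 1 of 11), Müller glia genes -0.21 (3 and 0 of 18) and neurogenic genes -0.21 (2 and 1 of 8), of which the last 2 lists turned to 0.12 and 0.24 by the mean, and neurogenic genes to 0.022 with members of at least 10 UMIs. Its highest ratios were Ly75 (113), Glt1d1 (55.2), Syndig1 (35.6), Hs6st3 (30.3), Syt7 (25.6), Nell1 (24.7), Elfn2 (22.9), Rian (20.1), Insyn1 (19.9), Meg3 (19.1), Palld (18.3) and Rbfox1 (15.7). Its lowest ran from Cngb3 (0.206) and Guca1b (0.238) through Klhl1 (0.297), Gnat1 (0.318), Pdia5 (0.350), AI847159 (0.355), Sap30 (0.362), Lrp4 (0.363), Frmpd1 (0.365), Dcdc2a (0.381) and Tmem26 (0.383) to Proser2 (0.390). Class 2 had a Müller-type profile relative to Rods, though most Müller genes were lower in it than in Müller glia (values in the last paragraph). Over Rods its Müller glia genes had a median of 5.40 (20 and 0 of 20) and rod genes -4.96 (0 and 24 of 24), with RGC general genes at 2.81 (13 and 2 of 16) and RGC transcription factors at 2.76 (13 and 1 of 16). Its Calb2 was at 4808 CPM and its Sncg at 1167 CPM. Among its highest ratios were C1ql4 (765 [136–30329], 1 UMI in Rods), Sfrp1, Nrg3os, Mctp1 at 514 against 1.45 CPM (353), Trarg1, Col1a2 (284), Bcan, Nab2, Serpinb8, Sfrp2 (245) and Cmtm5. The lowest were Cldn7 (0.0134), Cpm, Guca1b (0.0168), Pdzph1, Glp2r, Rdh8, Pde6a (0.0199), Rncr4, Shisa2, Radil, Slco4a1 and Impg1 (0.0247). Class 4, of 43 cells, had bipolar genes at a median of 2.47 (10 and 1 of 17) and rod genes at -3.98 (0 and 24 of 24) over Rods, with RGC general genes at 2.99 (7 and 2 of 11) axon growth genes at 3.61 (15 and 5 of 22) and excitability genes at 2.80 (10 and 2 of 15; -0.014 with members of at least 200 UMIs). Its highest were Cdh8 (534 [389–752]), Pde1a (467), Brinp3 (406), Scgn (400), Ptchd4 (336), Epha6 (289), Car3 (277), Erbb4 (265), Prr16 (242), Cntnap5a (207), Galntl6 (189) and Zfhx4 (132), and its lowest were Adcy1 (0.0163, 1 UMI), Cdkn1c, BC065403, Hs3st3b1, Plxna2, Synpo2, Pde6a, BC046251, Htra1, Cpt1a, Lrp4 and Plpp2. By median-of-ratios scaling the median gene of class 4 shifted by 0.32 over Rods and 0.15 over the GFP library. Of the 12 highest over Rods, 3 in class 1, 4 in class 2, 6 in class 4 and 4 in rgc-like cells were also among the 12 highest over the GFP library.

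Within the Pou4f2 library, cells with a Pou4f2 UMI had more RGC and less bipolar transcript than cells without (1283 against 7781 cells, each thinned to 2000 UMIs). Bipolar cells were 65 of the 1283 and 1334 of the 7781, and Rods 95 and 2935. Values over all cells thus do not separate class mix from levels within a class. GFP was at 2453 against 339 CPM, a ratio of 7.23 [6.97–7.50]. Sncg was at 470 against 85.3 CPM (5.52) and Calb2 at 1066 against 256 CPM (4.16). The other highest were Barhl1 (6.30), Islr2 (5.33), Fign (5.07), Pld5 (4.90), Opcml (4.89), Sox11 (4.48), Sez6l (4.25), Elavl2 (4.15) and Cpne4 (4.14), and among the lowest were Il1rapl2 (0.134), Cabp5 (0.150), Opn1sw (0.176), Adamtsl1 (0.220), Prss56 (0.222), Opn1mw (0.224), Pgc (0.230), Cdh9 (0.236), Sebox (0.240), Pde6h (0.242) and Fam135b (0.248). RGC general genes had a median of 1.51 (13 and 1 of 17), RGC transcription factors 0.96 (9 and 2 of 16), rod genes -0.52 (0 and 8 of 24), bipolar genes -1.50 (0 and 18 of 20) and Müller glia genes -0.38 (0 and 5 of 20). With at least 2 Pou4f2 UMIs the rod median was -0.92. Within single classes the RGC general median was 0.91 in Müller glia, 0.74 in Bipolar cells, 0.32 in class 1, 0.12 in Rods and -0.02 in rgc-like cells.

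The share of rgc-like cells was higher with more Pou4f2 UMIs: 6.59% at 0, 32.8% at 1, 57.0% at 2 to 3 and 90.3% at 4 or more UMIs. Mean RGC UMIs per thinned cell were 1.91 (SD 3.29), 3.54 (SD 5.16), 6.53 (SD 7.98) and 9.53 (SD 6.65) in these bins, and mean rod UMIs were 68.1, 54.4, 41.2 and 15.2. Within Rods mean rod UMIs were 132 at 0 and 131 at 1. Within class 1 they were 102, 104 and 93.1 in the first bins, and within rgc-like cells 35.9, 39.1, 34.7 and 14.5. Class mix differed between bins, so the means over all cells are not read as changes within a class. The SDs are over cells of 1 library. How the rgc-like label was made is not given, and it can rest on RGC genes, of which Pou4f2 is one, so the label itself can set this rise. The share of cells in own clusters found in the Pou4f2 library, made without Pou4f2 and GFP, was 32.0%, 79.5%, 96.1% and 98.4% in these bins. Those clusters include rod and Müller clusters with few or no rgc-like cells.

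**Figure D4:**
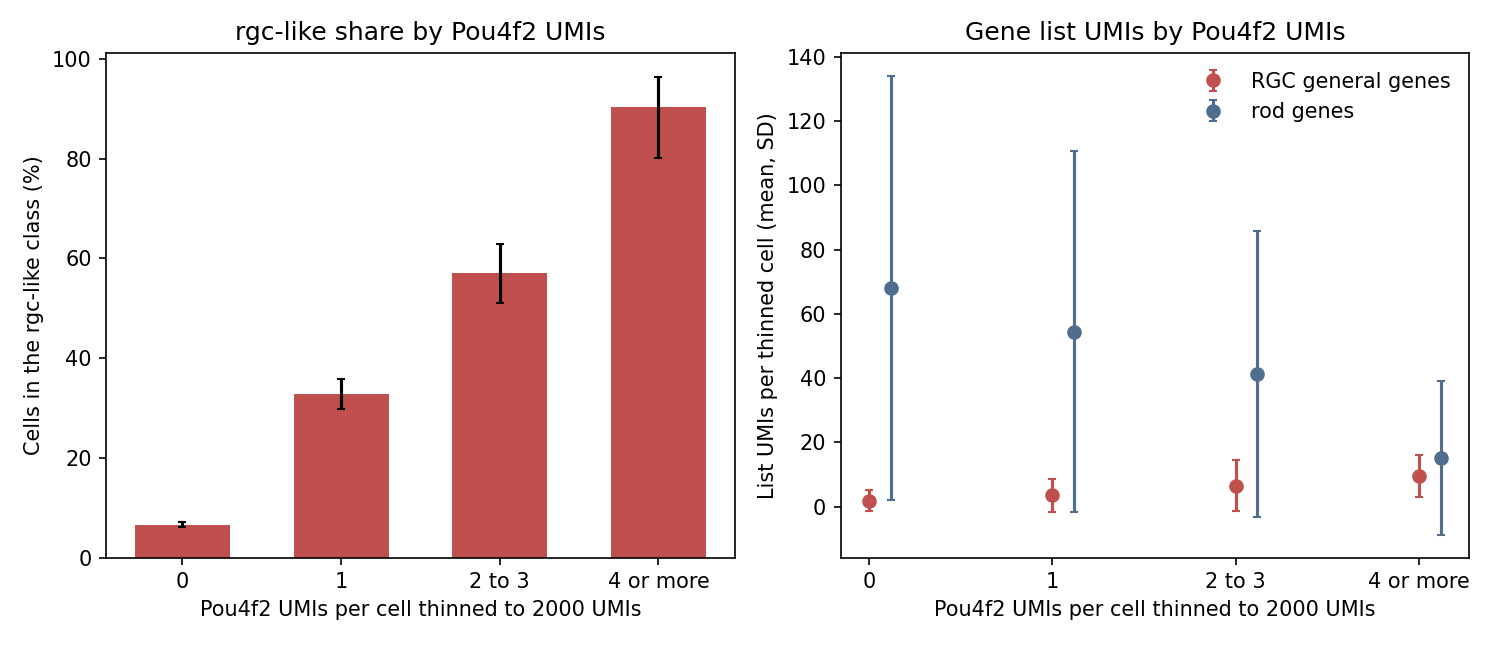
Left, rgc-like share of thinned cells, in percent, by Pou4f2 UMIs of the cell, with exact binomial 95% intervals. Right, mean RGC general and rod UMIs per thinned cell with the SD over cells; the rgc-like share was 6.59% at 0 and 90.3% at 4 or more UMIs, and the label can rest on RGC genes.

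UMIs of RGC and of rod genes were found together in single cells of both libraries. Rod UMIs were in 92.1% of thinned cells of the Pou4f2 library and 98.4% of the GFP library, and in 85.8% and 95.9% of Bipolar cells, so the joint share mostly follows that of RGC genes (56.7% and 37.5%). Background was not subtracted, and expression of both sets by one cell is not read from these shares. In thinned cells 50.4% [49.3–51.4] of the Pou4f2 library and 36.4% [35.3–37.5] of the GFP library had a UMI of both gene sets. The share was 77.6% in rgc-like cells, 83.1% in class 2, 38.8% in class 1, 27.5% against 20.2% in Rods, 49.6% against 19.7% in Müller glia, 77.4% against 85.4% in Bipolar cells, 82.4% against 80.6% in Amacrine cells and 43.2% against 36.6% in Cones. With at least 2 genes of each set the shares were 17.5% of the Pou4f2 library, 10.4% of the GFP library and 43.4% of rgc-like cells, and Amacrine cells turned to 43.9% against 56.1%. Bipolar cells, which should lack rod transcripts, had means of 5.33 rod UMIs in the Pou4f2 library and 7.78 in the GFP library, at median depths of 11361 and 12118.5 UMIs. Rgc-like cells had a mean of 35.5 and a median of 12 rod UMIs, and a mean of 7.32 and a median of 4 RGC UMIs. In Rods the means were 132 and 0.341 and the medians 125 and 0.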

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

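All tests of explanations in this part were chosen after the result they address had been seen, and with 1 library per group a difference between the pools of retinas stays open for each pattern.

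In barcodes outside the cell table, Pou4f2 was at 131 CPM in the Pou4f2 library (888 UMIs, in 8.68% of 2937 barcodes), against 0 UMIs in such barcodes of the GFP library. Of these UMIs, 608 were in the 91 barcodes with 25000 UMIs or more, at 222 CPM. Some genes differed in opposite directions between classes, Pou4f2 library over GFP library, and these differences between classes were not tested. The GFP ratio was 1.89 in Müller glia, 0.237 in Rods and 0.100 in Amacrine cells, but within the Müller cluster shared by both libraries it was 0.534 [0.487–0.585], the same direction as in Rods. The Npy ratio was 14.9 in Amacrine cells and 0.655 in Müller glia. The Rprm ratio was 2.70 in Bipolar cells and 0.250 in Amacrine cells.

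The first pattern is the 60 genes at least 4-fold higher in Müller glia of the Pou4f2 library. Free RNA was argued against by the Müller level over the lower of the Rod and Bipolar levels, with a median of 20.3 (quartiles 10.4 and 43.8), where free RNA alone would give about 1. A first form of this test, against the highest of 4 classes, gave 1.14 and was replaced after that value was seen, since 30 of the 60 genes were highest in Amacrine cells and 23 of those were also at 20 CPM or more in Amacrine cells of the GFP library. Cells of classes 1, 2, 4 or rgc-like carried in the Müller class, or doublets with them, were estimated to bring a median of 0.0799 of the excess. Each source's share was set near the least raised of its abundant genes, and was 0 for all but class 2 (2.77%). Less free RNA of such genes in this library can lower these shares. The estimate is thus no upper limit, and this explanation stays open. In Müller glia with over without a Pou4f2 UMI (124 against 1395 cells) the genes had a median log2 ratio of 1.01 [0.89–1.13]. This interval is over the 60 genes, taken as independent, and not over cells or pools. Carried cells or doublets that bear Pou4f2 can give the same direction, so the ratio does not separate them from a response. A response of Müller glia to the plasmid stays a hypothesis.

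The second pattern is the rgc-like class, at 11.3% of the Pou4f2 library and 0.0389% of the GFP library. Ganglion cells already present and not electroporated were argued against by GFP: 86.6% [84.4–88.6] of thinned rgc-like cells had a GFP UMI, against at most 16.7% in Rods, Bipolar cells, Amacrine cells and Cones. Doublets of other classes stay open: 7 of 40 RGC genes (Ebf1, Gap43, Klf7, Sox11, Stmn2, Tubb3 and Uchl1) were higher in rgc-like cells than in every other class, but the label itself may rest on RGC genes. Scrublet marked 2.79% [1.88–3.98] of rgc-like cells, 7.08% of class 2, 11.6% of class 4 and 6.18% of Müller glia of that library, and 2.76% of Müller glia of the GFP library. Of cells with 4 or more Pou4f2 UMIs, 98.4% lay in own clusters found in the Pou4f2 library, against 32.0% of cells with 0. These clusters include a rod cluster with 26 rgc-like cells of 1255 and a Müller cluster with 0 of 962. The share thus counts cells of any such cluster and not the rgc-like class alone. A response of rgc-like cells to the plasmid stays a hypothesis. The own clusters were made without Pou4f2 and GFP.

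The third pattern is GFP at 86.7 CPM in Rods of the Pou4f2 library against 366 CPM in Rods of the GFP library. A candidate explanation is that GFP-bearing cells of the rod lineage carry the label of class 1: over Rods and class 1 together GFP was at 323 against 366 CPM, a ratio of 0.884 [0.854–0.914]. Free RNA is also a candidate source of most GFP UMIs left in these Rods, since their variance over mean was 1.92, 1.31 times the median of 8 marker genes of other classes, and 19.3 in Rods of the GFP library. Whether such RNA gave all GFP of Rods, Bipolar cells, Amacrine cells and Cones stays open. Their highest mean per cell was 4.61 times the lowest, but median depths ran from 3708 to 11361 UMIs, the highest CPM was 1.79 times the lowest, and thinned shares with GFP were 14.3% to 16.7%. The test per cell was run first, and the others were added after its value was seen.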

How the results depend on the processing

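Of the alternatives, 3 were added after the data were seen: the first label column, Müller glia in the shared cluster only, and other reference cells for classes 2, 4 and rgc-like. No paired analysis was possible because each group has 1 library, and nothing can be said of the spread between pools. Of 874 alternative values for single genes, 723 stayed within the main interval, 148 moved and 3 reversed; of 809 for list medians the counts were 759, 33 and 17, and of 103 for shares 74, 29 and 0. These counts cover comparisons the text gives and not levels within 1 class, a set narrowed after the reversals were seen. Results not given in the text had 318 gene values (35 reversed) and 1288 list medians (18 reversed). A list median was counted as reversed only where its main percentile was extreme. Changes of sign in other lists were counted as stayed or moved. Of the 24 named genes over whole libraries, 17 stayed among them with cells thinned, 20 with all barcodes and 22 without doublets. Genes near 3 counts in one arm are limited by depth. For the values below the cause was not tested.

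Thinned to 1000 UMIs the share of cells with a Pou4f2 UMI was 8.26%, and with at least 2 UMIs 3.82%; the first keeps fewer UMIs of each cell and the second asks for more Pou4f2 UMIs, by construction. Own clustering put 53.7% of the Pou4f2 library in rod clusters and 22.8% in Müller clusters (435 cells of it in 1 cluster with 16 Müller markers and 14 of another list), and RGC general clusters held 4.52% of it and 1.02% of the GFP library. All 79 cells of the latter and 53 of the former lay in a cluster of mixed make-up: 74 of the 79 carried the Amacrine label and 29 of the 53 the rgc-like label. It had 13 RGC general markers and 10 of another list, and Nhlh2 and Prdm13 of the amacrine list and Ebf3 of the RGC general list led it. Its type stays open, and without it the share is 362 of 9187 cells of the Pou4f2 library and none of the GFP library. The RGC general cluster found in the Pou4f2 library, with 31.1% of rgc-like cells, over own rod clusters, with 43.5% of them in 1 cluster, gave medians of -4.75 for rod, -0.39 for Müller glia, -0.95 for proliferating and -0.61 for neurogenic genes. With cells thinned, the whole-library medians were -0.46 for rod, 0.17 for endothelial and 0.34 for pericyte genes, amacrine genes within Bipolar cells stood at 0.42, and bipolar and neurogenic genes within Müller glia at 0.068 and 0.0089. With members of at least 200 UMIs, axon growth genes within Rods stood at -0.025, amacrine genes within Bipolar cells at 0.45 and excitability genes in class 4 at -0.014. In the shared Müller cluster, the log2 ratio of GFP was -0.91, and Müller glia genes stood at 0.038, proliferating at -0.016 and neurogenic at 0.045. In thinned Cones the log2 ratios of Sncg and Stmn2 were each -0.56, from a few UMIs against the floor of 3. In class 1 over Rods the mean was 0.12 for Müller glia and 0.24 for neurogenic genes, and neurogenic genes with at least 10 UMIs gave 0.022. For cells with against without Pou4f2, RGC general genes stood at 1.76 and rod genes at -0.92 with at least 2 UMIs, and RGC general genes at 1.13 by the mean. With at least 2 genes of each set, RGC and rod genes were found together in 17.5% of the Pou4f2 library, 10.4% of the GFP library and 43.4% of rgc-like cells.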

Other observations

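Genes of some non-neuronal cell types other than Müller glia, and of cell state, also differed between whole libraries. Microglia genes had a median log2 ratio of 2.65 (7 higher and 0 lower of 11), from low levels: C1qb was at 8.54 CPM against 0 UMIs and C1qa at 5.53 against 0.0388 CPM. Astrocyte genes had a median of 0.97 (6 and 0 of 7), with Gfap at 11.01 against 1.03 CPM, and Aqp4 of that list is also a Müller gene. Within the shared Müller cluster the median of this list was 0.32 (2 and 0 of 7), and the share of Müller glia differed between libraries. The 0.97 is thus not read as a difference in astrocytes. Pericyte genes had a median of -1.53 (2 and 5 of 8), with Rgs5 at 4.88 against 21.5 CPM, endothelial genes -0.28 (1 and 3 of 10) and retinal pigment epithelium genes -0.03 (1 and 1 of 5). With cells thinned the pericyte and endothelial medians turned to 0.34 and 0.17. Class 3 held 335 of 363 Rgs5 UMIs of the Pou4f2 library and 1075 of 1108 of the GFP library. They lay in 13.0% of its 23 cells and 15.6% of its 45 cells, so the Rgs5 difference rests on few cells. The leading genes of class 3 were of microglia and vessels in the Pou4f2 library and of vessels in the GFP library. Immediate early and dissociation genes had a median of 0.67 (9 and 0 of 14), with Fos at 1040 against 467 CPM. Within Müller glia, which were 16.6% and 6.58% of the libraries, their median was -0.051 (0 and 0 of 14), with Fosb at 271 against 399 CPM. Over whole libraries the median was 0.08 (4 and 0 of 17) for stress and apoptosis genes. The red blood cell list had 2 members with enough UMIs and no median, with Alas2 at 1.57 against 2.62 CPM and Hbb-bs at 0.108 against 1.86 CPM.

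The rgc-like class was a mixture by the authors' first label: 470 cells (45.2%) carried class 1, 204 (19.6%) class 3, 164 (15.8%) class 2 and 132 (12.7%) class 4. Cells of first label 1 had Sncg at 95.9 CPM. Cells of first label 3 had the most Pou4f2 (1531 CPM) and GFP (7595 CPM), with Sncg at 1969 CPM. Cells of first label 2 had Calb2 at 2899, Sox11 at 752 and Rlbp1 at 295 CPM, and cells of first label 4 had Car3 at 1252 CPM. Sex-linked genes differed between the pools: Xist was at 865 against 162 CPM and Uty at 40.4 against 95.8 CPM, Eif2s3y at 59.8 against 132 CPM and Ddx3y at 34.4 against 74.4 CPM. The effect of that difference on other genes was not tested.

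Class 2 over Müller glia and class 4 over Bipolar cells were compared after the data were seen. Class 2 over Müller glia had RGC general genes at a median of 1.496 (13 and 0 of 16) and Müller glia genes at -1.20 (0 and 16 of 20). Class 4 over Bipolar cells had bipolar genes at -1.60 (1 and 13 of 20). In the Müller cluster found in the Pou4f2 library, Top2a was at 16.1 and Mki67 at 9.92 CPM, against 2.83 and 2.57 CPM in shared-cluster cells of that library. The clusters were made from expression, so such differences can follow from how cells were split.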
